A study of Homo sapiens with 8 samples.

How the data were processed

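PANC1, an established line grown from a human pancreatic carcinoma, was profiled by RNA sequencing in 4 untreated libraries and 4 libraries of cells kept for 72 h with 1 mM pilocarpine, an agonist of muscarinic acetylcholine receptors. Per the labels' protocols, total RNA was purified with an RNAqueous-Micro kit, samples with an RNA integrity number above 8 were used, and the RNA was amplified to cDNA with a NuGEN Ovation kit and processed with an Encore biotin module. Whether the replicates were separate cultures is not given in the sources used here, so every p-value measures only the spread between these samples, which may be technical.

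The authors deposited 1 table of whole-number read counts for 25559 gene symbols in 8 columns, with no normalisation, and each column was matched to its sample by the sample's title. No value column was left out, and every entry named a gene. Per the submitters' processing notes, the upstream tools were bcl2fastq 1.8.4, Bowtie2, TopHat2 2.04 and HTSeq 0.6.1. The only genome build those notes name is the mouse build mm9, whereas the deposited symbols are human, so the build behind the counts is unclear and no coordinates are given here. The counting mode, the use of strand and the annotation are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies, which ribosomal protein and histone genes have in number, could therefore have been left uncounted or assigned to another gene. The values of such genes are uncertain to that extent. Amplification from a small amount of RNA can change how well transcripts of different GC content and length are recovered, and this was measured for each library.

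Library totals ran from 18.7 to 27.8 M counts. A floor of 3 counts, the limit that a count of 0 allows, stood at 0.108 to 0.160 counts-per-million (CPM), depending on the library. Counts came from amplified cDNA without molecular identifiers, so floors cover counting error only. Pairs of libraries within each group differed by more than sampling noise, with a chi-square per degree of freedom of 3.83 to 11.8 among untreated and 33.2 to 144 among pilocarpine libraries over genes with at least 10 counts, and none was counted as a duplicate.

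Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 13925. Libraries were scaled by the trimmed mean of M values (TMM), and pilocarpine was compared with untreated by the robust quasi-likelihood F test, two-sided, with no replicate block. Benjamini-Hochberg adjustment was applied with a threshold of 0.05 on the adjusted p. A log2 fold change is positive where pilocarpine was higher and is given with its standard error (SE). CPM values are given as mean ± SD over n = 4 libraries.

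Gene groups were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 32 of 33 lists that had at least 2 tested members. The value given for a list is the median log2 fold change of its tested members, beside the number of members past the threshold over all genes and adjusted over the list alone. Each test was repeated with a correlation estimated from the data, and with fry. The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest rises and the 10 largest falls among called genes with all 4 pilocarpine libraries on one side of all 4 untreated libraries, a mean of at least 50 counts in the higher group and an established symbol. It also names up to 4 members with the smallest p from each list that passed, up to 2 called members from each other list, every muscarinic receptor and the 3 genes with the most counts. Of the genes that the rule names, 1 is not reported here. Genes outside this rule are marked as chosen after their values were seen.

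GC content and length were taken from GENCODE 29, from the longest protein-coding transcript of each symbol or, where there was none, the longest transcript. Of the table's genes, 21945 matched by current or older symbol. Length and GC content were available for 92.6% of tested genes and 96.5% of called genes. The trend of each library on both properties was fitted with smooth terms (mgcv 1.9.3) against the mean of all libraries in the fit. It was used as an offset in a further edgeR fit. The slopes given for each library are linear and were taken against the mean of the untreated libraries, or of the other untreated ones for an untreated library. That fit, the same fit without pilocarpine library 1 and a fit without pilocarpine libraries 3 and 4 were chosen after seeing the data. The other settings tried, fixed beforehand, were DESeq2 size factors, upper-quartile scaling, library totals alone, no count filter, at least 50 counts in 4 libraries, the DESeq2 1.42.0 test, limma-voom with quality weights, the replicate number as a block, removal of the 20 most abundant genes, and leaving out each library in turn. Adjusted p-values that DESeq2 left undefined, 1081 in number, stayed undefined.

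The procedure was tested on simulated counts for pilocarpine against untreated, with 200 seeded genes. With the spread of all 8 libraries (12797 genes), 26.9% of seeded 1.5-fold changes, 89.6% of 2-fold changes and 98.5% of 4-fold changes were recovered, and 10 of 12557 unchanged genes were called. With the spread of the untreated libraries and the measured GC and length trends (12826 genes), 2646 of 12586 unchanged genes were called. Removing the trend brought this to 10, with 94.0%, 97.0% and 98.5% of the seeded changes recovered at the same 3 fold sizes. The seeded trends were themselves fitted with the smooth terms that removed them, and the spread was the small one of the untreated libraries. These rates are therefore no measure of power in the real data. With the spread of all 8 libraries and no seeded trend, the fit with the trend removed recovered 28.4%, 89.6% and 98.5%. In that simulation, genes were drawn independently of each other, and the spread was measured without removing the trend. Its recovery and its unchanged genes called are therefore no measure for the real data either.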

Results

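Transcript levels were measured by RNA sequencing in PANC1 cells, a human pancreatic cancer line, without treatment (n = 4 libraries) and after 72 h with 1 mM pilocarpine, which activates muscarinic acetylcholine receptors (n = 4 libraries). Totals were 22.8, 24.7, 23.3 and 24.6 M counts in untreated libraries 1 to 4, and 21.8, 27.8, 18.7 and 27.3 M in pilocarpine libraries 1 to 4. Between 16902 and 17536 genes had counts in a library. The abundant transcripts RPS16, of the small ribosomal subunit, ACTG1, a cytoplasmic actin, and EIF4G2, a translation initiation factor, had the most counts. RPS16 rose from 5172 ± 426 to 10085 ± 3971 CPM (log2 fold change 0.96, SE 0.25, adjusted p = 0.0442). ACTG1 had a log2 fold change of 0.49 (SE 0.16, adjusted p = 0.0641) and EIF4G2 one of -0.36 (SE 0.14, adjusted p = 0.0802).

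The comparison of the groups ranks transcripts by their difference between the untreated libraries and those of cells kept 72 h with the agonist. The titles of the untreated samples give no vehicle and no culture time, so effects of these cannot be told apart from pilocarpine. Among genes with an established symbol, at least 50 counts in the higher group and all 4 pilocarpine libraries on one side of the untreated ones, the 10 that rose most and the 10 that fell most are named here. They included the simple epithelial keratin KRT7 (7.80 ± 0.845 to 19.0 ± 7.70 CPM, log2 fold change 1.28, SE 0.26) and the hair-type keratin KRT81 (log2 fold change 1.28, SE 0.24). The RNA polymerase subunit gene POLR2L (242 ± 25.3 to 593 ± 299 CPM) and the respiratory complex I gene NDUFS7 (25.5 ± 2.35 to 62.6 ± 31.9 CPM) each rose by 1.29 on the log2 scale (SE 0.31). REL, a subunit of NF-kB, fell from 5.37 ± 1.52 to 1.73 ± 1.20 CPM (log2 fold change -1.61, SE 0.40, adjusted p = 0.0440). GPR75, a G protein-coupled receptor, fell from 2.42 ± 0.616 to 0.928 ± 0.455 CPM (log2 fold change -1.38, SE 0.31). The metalloproteinase genes PAPPA (8.24 ± 1.26 to 4.18 ± 1.33 CPM) and MMP16 (14.6 ± 1.35 to 7.47 ± 3.65 CPM) fell by 0.97 and 0.96 on the log2 scale.

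The other large rises of this kind were in DPM3, a subunit of the enzyme that makes the mannose donor of glycosylation (log2 fold change 1.39, SE 0.29), EGFL7, a secreted protein known from endothelium (1.33, SE 0.22), and PCSK1N, an inhibitor of a prohormone convertase (1.40, SE 0.27). CDC42EP5, an effector of the GTPase CDC42 (1.43, SE 0.32), PDZD7, a scaffold protein (1.27, SE 0.21), and C9orf16 (1.24, SE 0.25) also rose. The other large falls of this kind were in the zinc finger genes ZNF724P (log2 fold change -1.21, SE 0.26), ZNF484 (-1.07, SE 0.18) and ZNF486 (-1.04, SE 0.19). ACER2, an alkaline ceramidase (-1.11, SE 0.32, adjusted p = 0.0494), ARMCX4 (-1.06, SE 0.26) and RFX3, a transcription factor of ciliated cells (-1.06, SE 0.23), fell as well. Adjusted p-values were 0.0432 for the 10 rises and 0.0432 to 0.0494 for the 10 falls. The 10 transcripts that rose had a GC content of 60.1% to 74.5%, and the 10 that fell one of 36.4% to 52.4%, against a median of 49.1% over all tested genes.

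In all, 1522 of 13925 tested genes passed edgeR's quasi-likelihood test, 1348 higher and 174 lower with pilocarpine, and 200 of them changed at least 2-fold. The smallest adjusted p was 0.0432, and 5989 genes had an unadjusted p under 0.05. Leaving out pilocarpine library 1 gave 7728 calls, which held all 1522. Leaving out any other library in turn (untreated library 1, 2, 3 or 4, pilocarpine library 2, 3 or 4) gave 0 calls, with 4011 to 5060 genes at an unadjusted p under 0.05. DESeq2 called 4394 genes (2597 higher) and limma-voom 7963 (4042 higher). Upper-quartile scaling left 588, and scaling by library totals alone left 0, with 5948 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0563.

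**Figure D1:**
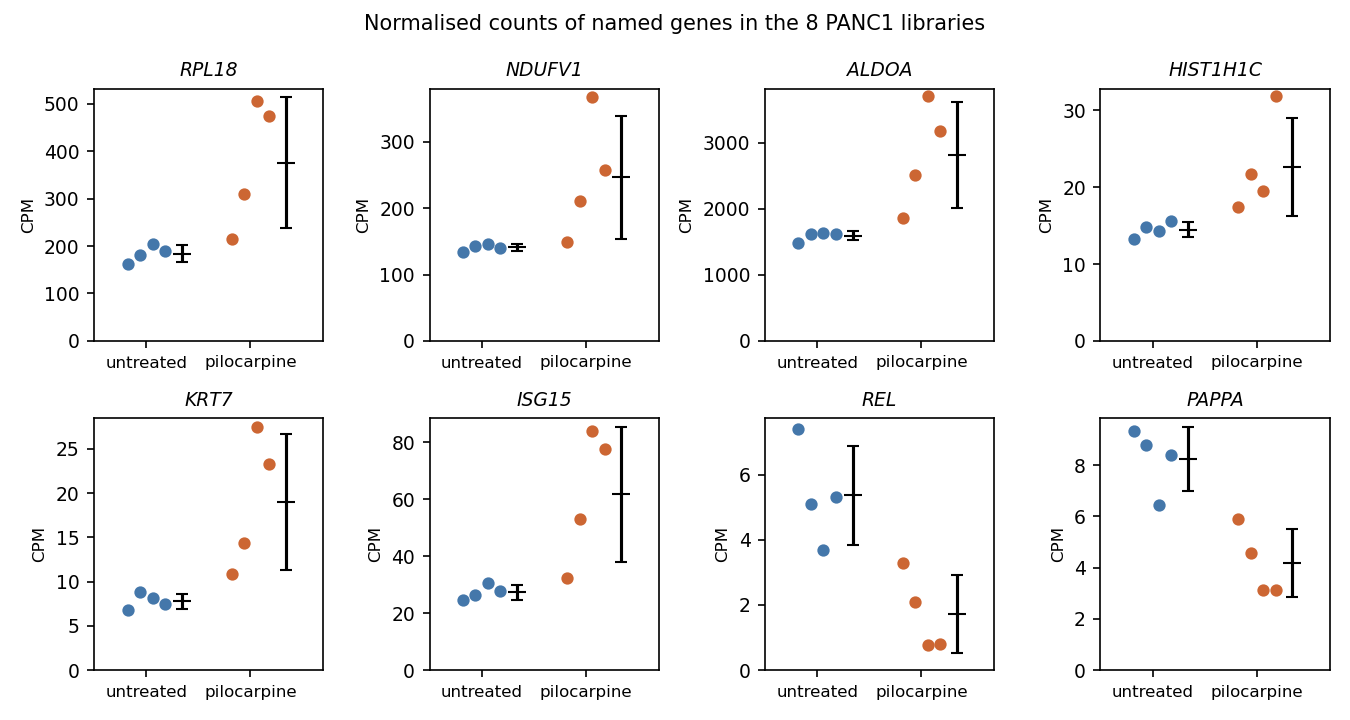
Normalised counts (CPM, vertical axes starting at 0) of 8 genes in the 4 untreated and 4 pilocarpine libraries, with points for libraries 1 to 4 from left to right, with mean and SD (n = 4) as a black bar. KRT7 has a mean of 7.80 CPM without and 19.0 CPM with pilocarpine, and in each of the 8 genes pilocarpine library 1 is the pilocarpine library nearest to the untreated mean.

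Higher GC content and shorter transcripts went with higher fold changes. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.694 with GC content and -0.568 with transcript length, and a fitted trend on both took up 62.0% of its variance. Called genes that rose had a median GC content of 62.0% and those that fell one of 42.5%. The slope on GC content, in log2 CPM per 10 percentage points, was 0.048 in pilocarpine library 1, close to the 0.067 of untreated library 2, and 0.302, 0.525 and 0.325 in pilocarpine libraries 2, 3 and 4. The group means of 0.300 ± 0.195 and 0 ± 0.0478 (SD, n = 4) gave p = 0.0571 in a two-sided exact permutation test, where the smallest possible p is 0.0286 (Benjamini-Hochberg 0.114 over 6 library measures). The slope on length was -0.128 ± 0.110 per doubling with pilocarpine and 0 ± 0.0538 without (exact permutation p = 0.114, Benjamini-Hochberg 0.171).

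With the GC and length trend of each library removed, genes that had risen kept a median log2 fold change of 0.19 (median SE 0.09), from 0.73 (0.18), and 1210 of the 1316 with GC and length values kept their sign. Genes that had fallen went from a median of -0.67 (SE 0.18) to -0.36 (0.12), and 150 of 153 kept their sign. In that edgeR fit REL had a log2 fold change of -1.13, GPR75 one of -1.49, PDZD7 one of 0.98 and KRT7 one of 0.60, each with an adjusted p of 0.0957. The fit called 0 of 12901 genes, with 3696 at an unadjusted p under 0.05, and no other tool was run with the trend removed. When pilocarpine library 1 was also left out, 3555 genes were called (1943 higher, 1612 lower), 598 of them among the 1522. The 10 largest rises and 10 largest falls of the kind named above were all among these, with KRT7 at 0.66 (adjusted p = 0.00446), EGFL7 at 0.68 (adjusted p = 0.00362), REL at -1.35 (adjusted p = 0.00466) and GPR75 at -1.91 (adjusted p = 0.00196). Leaving out the pilocarpine library nearest to the untreated ones narrows the spread within its group, so adjusted p-values of this fit can be too small. The named genes were picked from the same libraries, so their calls here are no independent support.

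**Figure D2:**
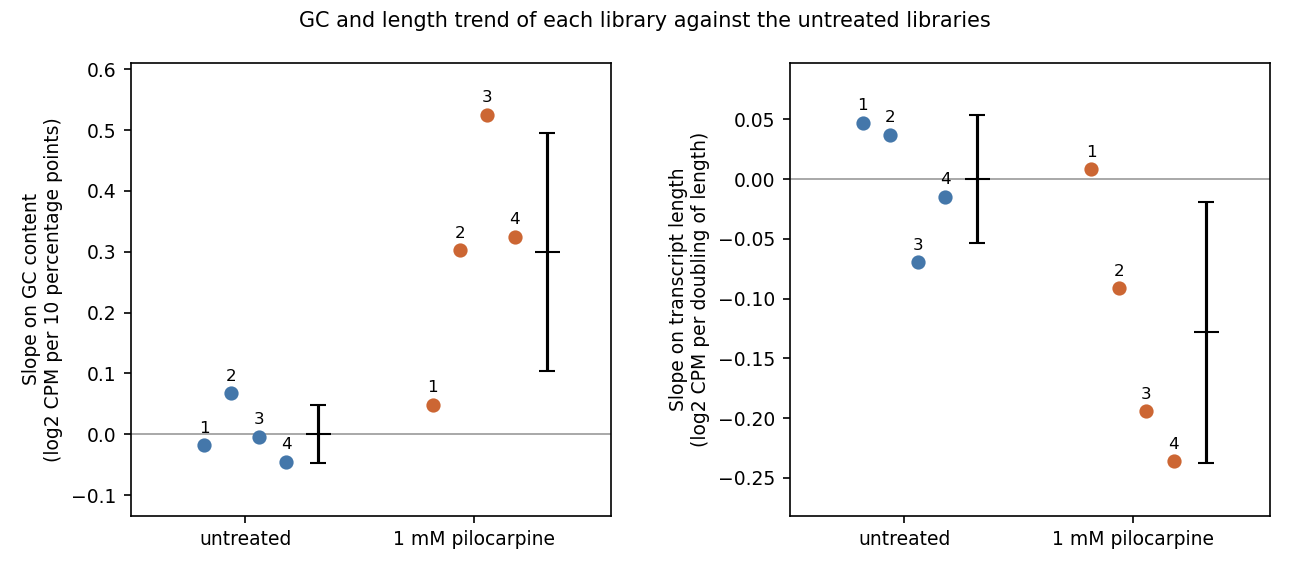
Slope of each library's log2 CPM on GC content (left, per 10 percentage points) and on transcript length (right, per doubling), relative to the mean of the untreated libraries; points are libraries numbered by replicate, and black bars give mean and SD (n = 4). Pilocarpine libraries 2, 3 and 4 have GC slopes of 0.302 to 0.525 and pilocarpine library 1 one of 0.048, within the span of the untreated libraries.

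Genes of cytosolic ribosomal proteins, the protein part of the translation machinery, rose as a group with pilocarpine. Of 40 tested members, 13 rose over all genes and 30 adjusted over the list alone, with a median log2 fold change of 0.66 (camera adjusted p = 4.4e-09). This call had an adjusted p = 0.652 with an estimated correlation. The list's mean log2 CPM was 8.33 in pilocarpine library 1, within the 8.18 to 8.44 of the untreated libraries, and 8.69 to 9.30 in pilocarpine libraries 2 to 4. RPL18 rose from 184 ± 17.6 to 376 ± 137 CPM (log2 fold change 1.03, SE 0.24), and RPL13 from 370 ± 35.2 to 744 ± 263 CPM (1.01, SE 0.23). RPS9 rose from 271 ± 25.3 to 510 ± 147 CPM (0.91, SE 0.19) and RPL35 from 183 ± 16.0 to 335 ± 102 CPM (0.87, SE 0.20). The adjusted p was 0.0432 for each. The members had a median GC content of 51.1% and a median length of 1184 nt, against 3362 nt over all tested genes. In the fit without the trend these 4 genes were at 0.39, 0.89, 0.38 and 0.28. Removal of the trend gave a list median of 0.33 (adjusted p = 5.2e-10, and 0.570 with an estimated correlation). In the fit that also left out pilocarpine library 1, 26 of 40 members rose.

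Nuclear genes of oxidative phosphorylation, which encode mitochondrial respiratory complexes, also rose as a group. Of 30 tested members, 2 rose over all genes, and adjusted over the list alone 8 rose and 1 fell, with a median log2 fold change of 0.30 (camera adjusted p = 0.0135). This call had an adjusted p = 0.694 with an estimated correlation. Of 10000 random lists matched on GC content, length and expression, 9.05% had a median at least as high as scaled. The rise as scaled was therefore not set apart from that of unrelated genes with these properties. With the trend removed, 0% of such lists reached the list's median of 0.22. Random lists draw unrelated genes, while this list had an estimated correlation of 0.623 as scaled, so both shares may be too small. The list's mean log2 CPM was 6.89 in pilocarpine library 1, within the 6.86 to 7.05 of the untreated libraries, and 7.12 to 7.55 in pilocarpine libraries 2 to 4. The complex I genes NDUFV1 (141 ± 5.49 to 246 ± 92.3 CPM, log2 fold change 0.81, SE 0.22) and NDUFB8 (99.6 ± 8.19 to 163 ± 49.0 CPM, 0.71, SE 0.20) rose with an adjusted p of 0.0472. The complex III gene UQCRC1 had a log2 fold change of 0.70 (SE 0.20, adjusted p = 0.0513) and the complex IV gene COX4I1 one of 0.81 (SE 0.24, adjusted p = 0.0528). Removing the trend put these 4 genes at 0.36, 0.24, 0.16 and 0.53. The median GC content was 47.8% and the median length 1660 nt. Leaving out pilocarpine library 4 ended the group's call (median 0.26, adjusted p = 0.0636). Without pilocarpine library 3 the median was 0.20, and without pilocarpine libraries 3 and 4 the median was 0.030 (adjusted p = 0.504). After removal of the trend it was 0.22 (adjusted p = 0.0026, and 0.775 with an estimated correlation), and 17 of 30 members rose when pilocarpine library 1 was also left out. The list of 13 mitochondrially encoded genes had 0 members among the counted symbols and was not tested.

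Genes of glycolysis and the hypoxia response rose as a group, with a median log2 fold change of 0.29 (camera adjusted p = 0.0178, and adjusted p = 0.652 with an estimated correlation). Of 32 tested members, 5 rose over all genes, and adjusted over the list alone 16 rose and 2 fell. The glycolytic enzyme genes ALDOA (1592 ± 69.1 to 2816 ± 801 CPM, log2 fold change 0.82, SE 0.19) and PFKL (99.1 ± 7.55 to 172 ± 49.5 CPM, 0.79, SE 0.18) rose. So did the lactate exporter SLC16A3 (388 ± 22.7 to 654 ± 156 CPM, 0.75, SE 0.16) and the lipase inhibitor ANGPTL4 (41.6 ± 2.92 to 68.4 ± 17.3 CPM, 0.72, SE 0.17). Adjusted p-values were 0.0432 to 0.0440. The median GC content of the list was 53.9%. Without the trend the median was 0.14 (adjusted p = 0.0079, and 0.570 with an estimated correlation), and ALDOA, PFKL, SLC16A3 and ANGPTL4 had log2 fold changes of 0.20, 0.31, 0.47 and 0.071.

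Replication-dependent histone genes, transcribed in S phase, rose as a group, with a median log2 fold change of 0.53 (camera adjusted p = 0.0159, and adjusted p = 0.652 with an estimated correlation). Of the 29 listed members only 13 were tested, and of these 2 rose over all genes and 5 adjusted over the list alone. HIST1H1C rose from 14.5 ± 0.946 to 22.6 ± 6.42 CPM (log2 fold change 0.64, SE 0.18, adjusted p = 0.0472) and HIST1H2BK from 62.3 ± 1.90 to 88.4 ± 16.6 CPM (0.50, SE 0.14, adjusted p = 0.0469). HIST1H2BD had a log2 fold change of 0.62 (SE 0.19, adjusted p = 0.0596) and HIST1H2AE one of 0.85 (SE 0.29, adjusted p = 0.0659). The members were short, with a median length of 950 nt and a median GC content of 48.8%. Without pilocarpine library 1 the group's adjusted p was 0.0674 and its median 0.60. Removing the trend gave an adjusted p of 0.231 and a median of 0.34, and HIST1H1C, HIST1H2BK, HIST1H2BD and HIST1H2AE had log2 fold changes of 0.073, -0.14, 0.39 and 0.34.

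Of the muscarinic receptors themselves, transcripts of CHRM3 and CHRM4 were counted in every library, at low levels. CHRM3 had 22, 37, 21 and 30 counts without and 28, 20, 20 and 17 counts with pilocarpine (1.11 ± 0.270 and 0.951 ± 0.312 CPM, log2 fold change -0.26, SE 0.28, adjusted p = 0.476). CHRM4 had 32, 29, 39 and 28 counts without and 19, 40, 34 and 37 with pilocarpine (1.31 ± 0.227 and 1.43 ± 0.471 CPM, 0.11, SE 0.25, adjusted p = 0.754). After removal of the trend these values changed sign, to 0.18 and -0.52 (adjusted p = 0.664 and 0.115). Over single libraries left out, CHRM3 ran from -0.45 without pilocarpine library 1 to -0.10 without untreated library 2. CHRM4 was also negative without pilocarpine library 3, at -0.066. CHRM1 had 2 counts, CHRM2 1 count and CHRM5 3 counts summed over the 8 libraries, so differences in them were not detectable at this depth. The list of muscarinic receptors, with these 2 tested members, had a median of -0.076 (adjusted p = 0.879; -0.22 without pilocarpine library 3, -0.0019 without pilocarpine library 4). The tests of edgeR, DESeq2 and limma-voom called 0 of them, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

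Among signalling genes downstream of such receptors, the store-operated calcium channel ORAI1 rose from 35.4 ± 2.08 to 60.6 ± 19.5 CPM (log2 fold change 0.77, SE 0.20, adjusted p = 0.0452) and the calcium pump ATP2A3 from 6.49 ± 0.782 to 9.65 ± 1.62 CPM (0.57, SE 0.15, adjusted p = 0.0453). With the trend removed, ORAI1 was at 0.019 and ATP2A3 at 0.29. The list of calcium and G protein signalling, with 3 of 32 members higher over all genes and 3 adjusted over the list alone, had a median of -0.036 (adjusted p = 0.354; -0.15 without pilocarpine library 1, -0.0094 without untreated library 1, -0.062 with the trend removed). In the list of MAPK output, IER3, an early response gene (394 ± 28.1 to 578 ± 87.3 CPM, log2 fold change 0.55, SE 0.13), and UPP1, a uridine phosphorylase (110 ± 7.07 to 190 ± 57.9 CPM, 0.78, SE 0.20), rose. They were the 2 of 22 called members both over all genes and adjusted over the list alone. That list had a median of -0.013, a mean of 0.011 and a test direction of lower (adjusted p = 0.959; median -0.044 without pilocarpine library 2, 0.0050 without pilocarpine library 1). IER3 had a GC content of 58.5% and, with the trend removed, a log2 fold change of 0.0030 (adjusted p = 0.989), and UPP1 was at 0.39 (adjusted p = 0.0957).

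Immediate early genes, among them EGR1 and FOS, had a median log2 fold change of -0.069 (17 tested, adjusted p = 0.551), which ran from -0.20 without untreated library 4 to 0.036 without untreated library 2 and was -0.27 with the trend removed (adjusted p = 0.0025, and 0.570 with an estimated correlation). In edgeR 0 members were called, also 0 adjusted over the list alone, with 7 at an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 10. EGF receptors and ligands had a median of -0.32 (9 tested, adjusted p = 0.244). It was -0.15 without pilocarpine library 3, -0.48 without pilocarpine library 1 and -0.036 with the trend removed. Of these genes, 0 were called over all genes and 3 were lower adjusted over the list alone, with 4 at an unadjusted p under 0.05, 4 called by DESeq2 and 6 by limma-voom. FOXO targets, which rise when PI3K and AKT activity is low, had a median of -0.063 (19 tested, adjusted p = 0.354; -0.15 without pilocarpine library 1, -0.032 without pilocarpine library 3, 0.015 with the trend removed). There were 0 called over all genes and 0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 4 by DESeq2 and 9 by limma-voom. Cancer stem cell markers had a median of -0.16 (12 tested, adjusted p = 0.146; -0.25 without pilocarpine library 1, -0.087 with the trend removed). Of these markers, 0 were called over all genes and 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 6 by limma-voom. YAP-TEAD targets had a median of -0.21 (23 tested, adjusted p = 0.0977; -0.34 without pilocarpine library 1). Their median was -0.16 with the trend removed (adjusted p = 0.0026, and 0.570 with an estimated correlation). Of these targets, 0 were called over all genes and 0 adjusted over the list alone, 11 at an unadjusted p under 0.05, 7 by DESeq2 and 14 by limma-voom. Genes of acetylcholine handling and nicotinic receptors had a median of 0.17 (7 tested, adjusted p = 0.618; 0.016 without pilocarpine library 2, -0.013 with the trend removed). In edgeR 0 were called over all genes and 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2 and 3 by limma-voom. Median GC contents of these lists lay between 45.9% (FOXO targets) and 56.3% (acetylcholine handling and nicotinic receptors).

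In the cell cycle lists, CDT1, a replication licensing factor, rose from 44.9 ± 4.16 to 74.3 ± 23.0 CPM (log2 fold change 0.73, SE 0.20, adjusted p = 0.0472). It was the 1 called gene of 36 in the list of G1/S and DNA replication, with 0 adjusted over the list alone (15 at an unadjusted p under 0.05, 8 by DESeq2, 21 by limma-voom), and the list median was -0.050 (adjusted p = 0.416; -0.076 without untreated library 2, -0.014 without untreated library 4). Removal of the trend put CDT1 at 0.25 (adjusted p = 0.202). Genes of G2/M and mitosis had a median of -0.13 (40 tested, adjusted p = 0.164), and one of -0.11 with the trend removed (adjusted p = 0.0418, and 0.770 with an estimated correlation). As scaled, 0 were called by edgeR over all genes and 0 adjusted over the list alone, 22 at an unadjusted p under 0.05, 16 by DESeq2 and 26 by limma-voom. Of 19 p53 targets, 3 rose over all genes and 6 adjusted over the list alone. Among them were FDXR, a mitochondrial reductase (16.4 ± 0.758 to 27.6 ± 5.56 CPM, log2 fold change 0.75, SE 0.15), and BAX, a pro-apoptotic protein (41.6 ± 2.01 to 65.9 ± 14.7 CPM, 0.66, SE 0.15). The list's median was 0.14 (adjusted p = 0.298; -0.021 with the trend removed). FDXR and BAX had a GC content of 64.3% and 58.9%, and log2 fold changes of 0.12 and 0.070 with the trend removed.

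Enzymes of cholesterol synthesis rose in part. Of 23 tested members of that list, 5 rose over all genes, and adjusted over the list alone 7 rose and 1 fell. MVD (55.2 ± 7.27 to 108 ± 29.8 CPM, log2 fold change 0.96, SE 0.19) and DHCR7 (166 ± 24.6 to 251 ± 26.05 CPM, 0.60, SE 0.13) had the smallest p. The list median was 0.18 (adjusted p = 0.146, and 0.694 with an estimated correlation; 0.25 and 0.0473 without pilocarpine library 3, 0.11 without pilocarpine library 4, 0.13 with the trend removed). SREBF1, the transcription factor of lipid synthesis (78.9 ± 14.2 to 127 ± 9.54 CPM, log2 fold change 0.68, SE 0.14), and the desaturase FADS2 (195 ± 43.2 to 312 ± 69.4 CPM, 0.67, SE 0.19) rose. They were the 2 of 15 called genes of fatty acid synthesis over all genes and adjusted over the list alone. That list had a median of -0.085, while its mean was 0.045 and its test direction higher (adjusted p = 0.959). Its median was -0.16 without pilocarpine library 1, 0.024 without pilocarpine library 3 and 0.11 with the trend removed. MVD, DHCR7, SREBF1 and FADS2 had a GC content of 58.3% to 65.6%, and with the trend removed they were at 0.27, 0.26, 0.35 and 0.39.

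Lysosomal genes GAA (13.7 ± 1.77 to 23.3 ± 3.61 CPM, log2 fold change 0.77, SE 0.14) and CTSA (166 ± 4.03 to 258 ± 39.9 CPM, 0.64, SE 0.12) rose. Of 32 members of the lysosome and autophagy list 6 rose over all genes, and adjusted over the list alone 13 rose and 5 fell. The median was 0.27 (adjusted p = 0.0519, and 0.652 with an estimated correlation; it passed without untreated library 1 or 2 or pilocarpine library 2 or 3, at 0.0218 to 0.0465). With the trend removed it was 0.087 (adjusted p = 0.0418, and 0.570 with an estimated correlation). DDIT4, a stress-induced inhibitor of mTORC1 (91.9 ± 13.2 to 159 ± 43.0 CPM, 0.79, SE 0.19), and the transcription factor ATF5 (132 ± 4.26 to 180 ± 26.9 CPM, 0.45, SE 0.12) rose. They were the called 2 of 40 genes of the unfolded protein response and ATF4 list, with 0 adjusted over the list alone (13 at an unadjusted p under 0.05, 10 by DESeq2, 22 by limma-voom). That list's median was 0.062 (adjusted p = 0.605; 0.018 without pilocarpine library 3, -0.044 with the trend removed). HSPB1, a small heat shock protein, rose from 239 ± 29.7 to 479 ± 147 CPM (1.00, SE 0.21). It was the 1 of 13 called genes of the heat shock list, over all genes and adjusted over the list alone. The heat shock list had a median of -0.022, a mean of 0.12 and a test direction of higher (adjusted p = 0.694; median -0.067 without untreated library 2, 0.029 without untreated library 4). These 5 genes had a GC content of 57.7% to 64.5%. Without the trend GAA was at 0.38, CTSA at 0.23, DDIT4 at 0.28, ATF5 at -0.052 and HSPB1 at 0.21.

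Interferon-induced genes rose in part. Of 29 tested genes of the type I interferon response, 8 rose over all genes and 8 adjusted over the list alone. They included ISG15, a ubiquitin-like modifier (27.4 ± 2.63 to 61.7 ± 23.6 CPM, log2 fold change 1.17, SE 0.25), and IFI6 (16.9 ± 2.18 to 32.2 ± 8.22 CPM, 0.93, SE 0.19). The list median was 0.34 (adjusted p = 0.0688, and 0.652 with an estimated correlation; it passed without untreated library 1 or 2 or pilocarpine library 2 or 3, at 0.0220 to 0.0476, and the median was 0.15 without pilocarpine library 4). Its median GC content was 51.4%. In the fit without the trend, the list median was 0.23 (adjusted p = 0.0066, and 0.570 with an estimated correlation), ISG15 was at 0.37 and IFI6 at 0.38. In the list of NF-kB and inflammatory cytokines, 3 of 27 members rose over all genes and 3 adjusted over the list alone. They included the cytokine genes CSF2 (3.67 ± 0.380 to 7.64 ± 1.88 CPM, 1.06, SE 0.19) and IL32 (76.1 ± 7.25 to 138 ± 42.3 CPM, 0.86, SE 0.20). The median of this list was 0.28 (adjusted p = 0.0688, and 0.659 with an estimated correlation; it passed without untreated library 1 or 2 or pilocarpine library 3, at 0.0220 to 0.0338). It was 0.051 with the trend removed, CSF2 0.76 and IL32 0.34.

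Epithelial markers rose in part, with 8 of 23 members higher over all genes, and 11 higher and 3 lower adjusted over the list alone. Beside KRT7, the simple epithelial keratin KRT8 rose from 417 ± 34.7 to 712 ± 165 CPM (log2 fold change 0.77, SE 0.16). The list median was 0.17 (adjusted p = 0.164, median GC content 57.0%). It ran from 0.037 without untreated library 4 to 0.33 without untreated library 2, and was -0.0095 with the trend removed, with KRT8 at 0.56. Of 24 mesenchymal markers, S100A4, a calcium-binding protein, rose over all genes (83.2 ± 8.62 to 146 ± 47.6 CPM, 0.81, SE 0.21). In this list 0 rose or fell adjusted over the list alone (9 at an unadjusted p under 0.05, 7 by DESeq2, 11 by limma-voom). The median was 0.11 (adjusted p = 0.551; 0.073 without pilocarpine library 2). It was -0.020 with the trend removed, and S100A4 was at 0.39. Of 22 NRF2 targets, which respond to oxidative stress, 7 rose over all genes, and adjusted over the list alone 8 rose and 1 fell. The ferritin heavy chain gene FTH1 (811 ± 57.7 to 1478 ± 436 CPM, 0.87, SE 0.20) had the smallest p. The median was 0.30 (adjusted p = 0.164; 0.20 without pilocarpine library 3). With the trend removed it was 0.12 (adjusted p = 0.0499, and 0.694 with an estimated correlation), and FTH1 was at 0.57. In the list of xenobiotic metabolism, GSTP1, a glutathione transferase, rose (322 ± 15.1 to 600 ± 218 CPM, 0.90, SE 0.23) and ABCC4, an exporter, fell (104 ± 6.59 to 71.4 ± 16.3 CPM, -0.55, SE 0.15). Adjusted over the list alone 3 of 14 rose and 4 fell, with a median of -0.0064 (adjusted p = 0.551; -0.089 without pilocarpine library 4, -0.093 with the trend removed). GSTP1 had a GC content of 63.7% and a log2 fold change of 0.095 with the trend removed. ABCC4 had a GC content of 42.6% and a log2 fold change of -0.18 with the trend removed.

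Most markers of other cell types were below the count filter. The leukocyte genes CD14 (0.690 ± 0.122 to 1.47 ± 0.527 CPM, log2 fold change 1.05, SE 0.28) and CORO1A (3.97 ± 0.461 to 6.83 ± 1.90 CPM, 0.77, SE 0.20) rose. They were the 2 of 5 tested markers called over all genes with 3 adjusted over the list alone (median 0.35, adjusted p = 0.164; 0.23 without pilocarpine library 3, 0.060 with the trend removed). EGFL7 was the 1 of 4 tested endothelial markers that rose over all genes, with 2 adjusted over the list alone (median 0.36, adjusted p = 0.164; -0.094 with the trend removed). Pancreatic acinar markers had 2 tested of 21 members and a median of 0.13 (adjusted p = 0.933; 0.34 without pilocarpine library 4, 0.075 without pilocarpine library 2, -0.24 with the trend removed), with 0 called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 in edgeR, 0 by DESeq2 and 1 by limma-voom. Pancreatic endocrine and neuroendocrine markers had 7 tested of 22 and a median of 0.25 (adjusted p = 0.551; 0.13 without pilocarpine library 4, 0.074 with the trend removed), with 0 called over all genes, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2 and 4 by limma-voom. Of 9 nuclear and snoRNA host long noncoding RNAs, taken as a sign of RNA quality, KCNQ1OT1 fell over all genes (6.04 ± 0.877 to 3.30 ± 1.11 CPM, -0.88, SE 0.24, adjusted p = 0.0473). In that list 1 rose and 2 fell adjusted over the list alone, and the median was -0.24 (adjusted p = 0.354; -0.11 with the trend removed). With the trend removed, CD14 was at 0.59, CORO1A at 0.13 and KCNQ1OT1 at -0.28, none past the threshold.

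**Figure D3:**
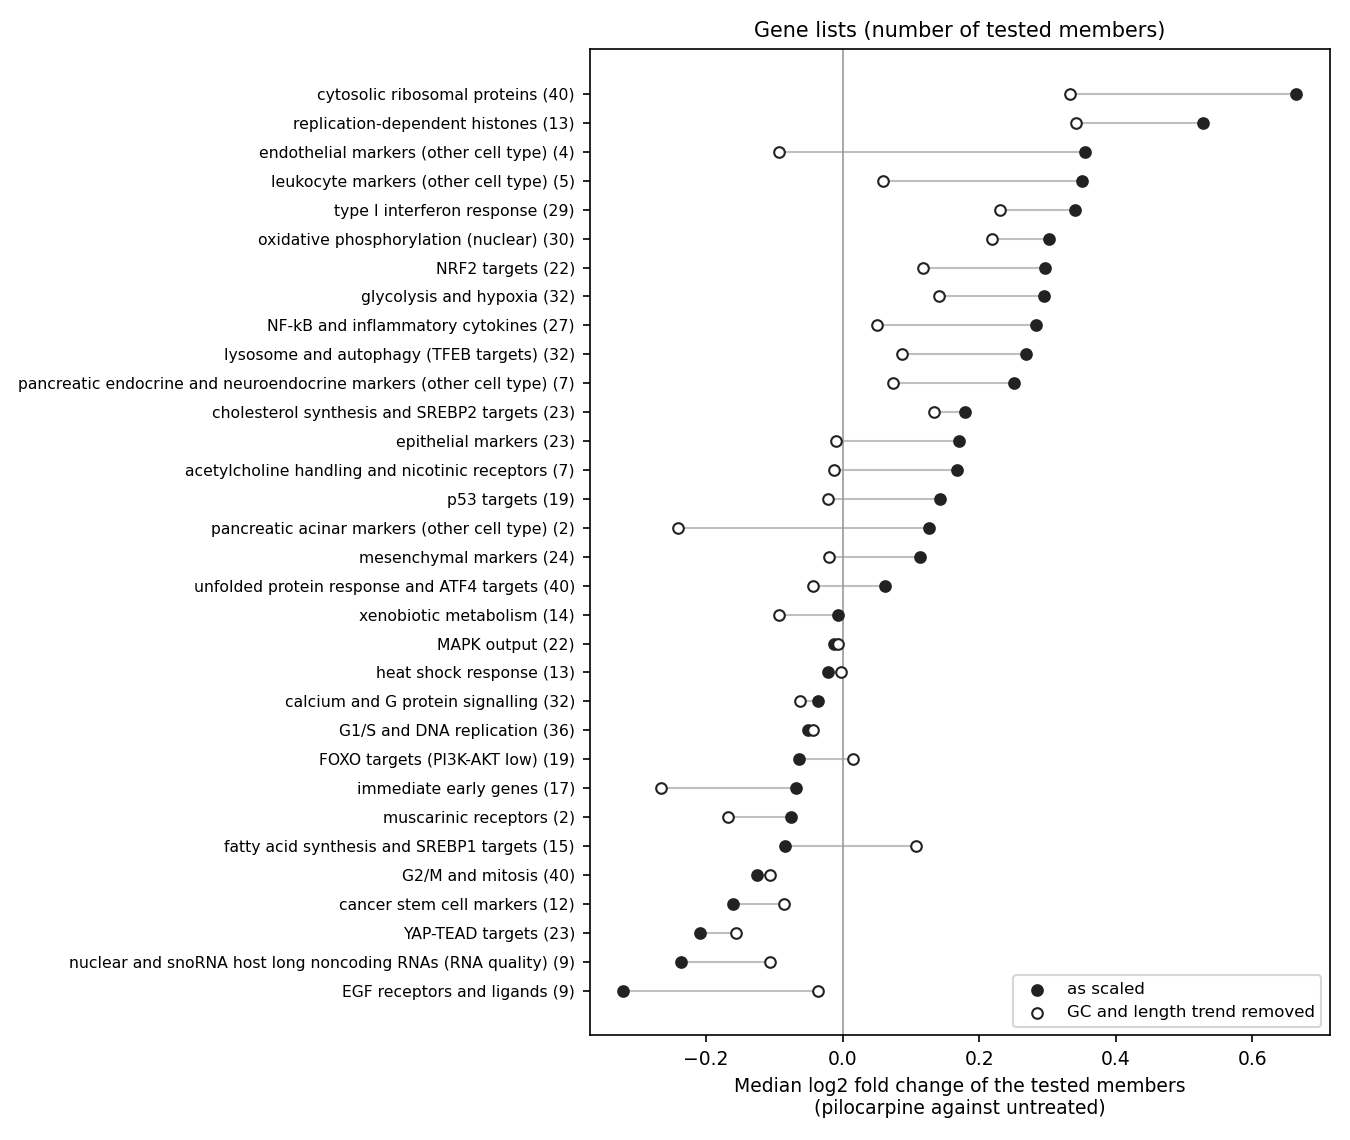
Median log2 fold change (horizontal axis, pilocarpine against untreated) of the tested members of 32 gene lists, with the number of tested members in parentheses; filled circles give libraries as scaled and open circles the fit with the GC and length trend removed. Cytosolic ribosomal proteins lie at 0.66 as scaled and 0.33 with the trend removed, and YAP-TEAD targets at -0.21 and -0.16.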

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

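The tests of sequencing depth, of a shared batch and of an exchange of 2 libraries, and every fit with the GC and length trend removed, were chosen after the results they concern were seen; the other tests in this part were chosen before. In 7 of 214 groups of 4 values, 1 library stood apart from the other 3 by Dixon's criterion, which chance meets in about 5% of groups. ALDOA was at 1489 CPM in untreated library 1, against a mean of 1626 CPM in the other 3. BAX was at 38.6 CPM in untreated library 1, against 42.6 CPM. HIST1H2BD was at 18.3 CPM in untreated library 3, against 15.0 CPM. The mean log2 CPM of the muscarinic receptor list was 0.70 in pilocarpine library 3, against 0.12 in the other pilocarpine libraries. The FOXO target list had a mean log2 CPM of 4.92 in untreated library 4, against 5.07. The replication-dependent histone list had a mean log2 CPM of 1.63 in untreated library 1, against 1.71. The list of nuclear and snoRNA host long noncoding RNAs had a mean log2 CPM of 5.69 in pilocarpine library 4, against 6.02.

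The 8 libraries can be split into 4 and 4 in 35 ways. For the count of called genes, 2 of the 35 splits gave as many as the real one, itself included (1522, and 3177 in the highest other split), so chance was not excluded. The same held for genes higher (1348, 2 splits) and lower (174, 2 splits): that other split had 1771 genes on one side and 1406 on the other, and since its direction is arbitrary the larger side was compared. The split with 3177 calls exchanges untreated library 3 and pilocarpine library 1, and each of the other 33 gave at most 1, which points to a structure of the samples. For the median log2 fold change, 1 of 35 splits was as large for histones (0.53, highest other 0.45), for glycolysis and hypoxia (0.29, highest other 0.25) and for cytosolic ribosomal proteins (0.664, highest other 0.663), by a margin of under 0.01 for the ribosomal list. This is the smallest share that 35 splits can give, in lists chosen because they had passed under these labels. It is under 0.05 for each list alone, but after correction over the 7 results (Benjamini-Hochberg 0.0667) chance was not excluded. For oxidative phosphorylation 9 of 35 splits were as large (0.30, highest other 0.37), so chance was not excluded.

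Fold changes followed GC content (Spearman correlation 0.694) and transcript length (-0.568). A few dominant genes (1522 calls without the 20 most abundant ones, 1518 of them shared) and lower depth were argued against, the latter by pilocarpine library 2, which had the largest total, 27.8 M counts, and a GC slope of 0.302. A GC and length bias of the libraries stays a candidate explanation, because the trend fitted on all other genes predicted the fold changes within ribosomal, oxidative phosphorylation and G2/M genes, with a lowest Spearman correlation of 0.619 (permutation p = 3e-05). Removing the trend ended every call: the median fold shrank by more than its SE among genes that had risen, from 0.73 (SE 0.18) to 0.19 (0.09), and fallen, from -0.67 (0.18) to -0.36 (0.12), and with 3696 genes at an unadjusted p under 0.05, against 5989, the smallest adjusted p was 0.0957, also for GPR75, whose fold grew (-1.38 to -1.49). An effect of pilocarpine that itself runs along GC content and length stays open as well and was not tested.

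Pilocarpine library 1 lay near the untreated libraries, at -20.1 on the first principal component, against -33.1 to -17.9 in the untreated and 16.4 to 58.2 in the other pilocarpine libraries. An untreated culture under a pilocarpine label stays a candidate explanation: with the trend removed, library 1 lay on the side of libraries 2 to 4 for 36.3% of the genes they shared above the others, while untreated library 3 did so for 39.9%; as scaled, library 1 did so for 45.5%, above the 6.31% to 27.7% of the untreated libraries, but for 24.9% of the genes they shared below the others, against 48.0% in untreated library 3. Gene lists with the trend removed were mixed on this. In 5 of 32 lists all pilocarpine libraries had a mean above all untreated ones, none past correction. For the type I interferon response, library 1 was at 0.20 and the highest untreated library at 0.074. For cytosolic ribosomal proteins (0.026) and oxidative phosphorylation (-0.054), library 1 lay within the untreated span. An exchange with untreated library 3 stays open too, but it was raised by the 3177 calls of that split, which are therefore no independent support. Untreated library 3 had the highest untreated score on that component, -17.9, still below the 16.4 to 58.2 of pilocarpine libraries 2 to 4. Its GC slope of -0.0043 lies within the span of the other untreated libraries. Its chi-square per degree of freedom against these was 5.77 to 11.8, and pairs of pilocarpine libraries had 33.2 to 144. A batch shared by pilocarpine libraries 2 to 4, with GC slopes of 0.302 to 0.525, stays a candidate explanation. Library 1 has the same treatment label, but its GC slope (0.048) lies within the untreated span, as such a batch would predict. A weaker response to pilocarpine in the culture of library 1 would predict this as well and stays open. Because the labels give no batches, a batch cannot be told apart from the treatment in libraries 2 to 4.

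Ribosomal protein genes had a median log2 fold change of 0.33 after the trend was removed (adjusted p = 5.2e-10, and 0.570 with an estimated correlation). An exact permutation test on the list's mean per library gave p = 0.0857 (Benjamini-Hochberg 0.244). A remainder of the bias along the annotated GC content and length was argued against, since random lists matched on these and on expression had medians of up to 0.14 within their central 95%. Trend and matching both used the longest annotated transcript, such as 4498 nt for RPL13, which kept 0.89. A bias that these lengths miss could not be seen by this test. Random lists draw unrelated genes, while the ribosomal list had an estimated correlation of 0.864 as scaled, so their range may be too narrow. A property of pilocarpine libraries 2 to 4 that library 1 lacks stays a candidate explanation, with the ribosomal mean of library 1 at 0.026 relative to the untreated mean (log2), below the highest untreated library at 0.07, and those of libraries 2 to 4 at 0.20 to 0.59. Whether that property is the treatment or the preparation of the libraries stays open.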

How the results depend on the processing

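The fits with the GC and length trend removed and the fit without pilocarpine libraries 3 and 4 were chosen after the data were seen, and all others before; where no cause is named, the cause was not tested. The counts of called genes, 1522 in all, 1348 higher and 174 lower, stayed within 1.5 times under DESeq2 size factors (1436), a minimum of 50 counts (1460) and removal of the 20 most abundant genes (1522). Without a count filter 1911 were called, and those lower were 435. Upper-quartile scaling gave 588 (526 higher, 62 lower), and library totals alone gave 0, 0 higher and 0 lower. DESeq2 called 4394 (2597 higher, 1797 lower) and limma-voom 7963 (4042 higher, 3921 lower). Removing the trend gave 0 in edgeR (0 higher, 0 lower, 3696 at an unadjusted p under 0.05), and leaving out pilocarpine library 1 as well gave 3555 (1612 lower). Leaving out pilocarpine libraries 3 and 4 gave 0 (0 higher, 0 lower, 2751 at an unadjusted p under 0.05), with fewer samples. Leaving out single libraries gave 0 to 7728 calls, 0 to 4006 higher and 0 to 3722 lower, the highest in each case without pilocarpine library 1 and 0 without each of the other 7. With the replicate number as a replicate block, 4394 genes were called (2355 higher, 2039 lower), including all 1522, and no list changed its side of the threshold. The numbers were not shown to pair the samples: the deviations of same-numbered libraries correlated at 0.358, 0.036, 0.220 and -0.013, and 3 libraries were closest to their own number. Of the 70 genes followed across settings, all but 5 kept their direction in each setting that gave them a value, 18 to 20 of the settings per gene. With the trend removed, HIST1H2BK was at -0.14, ATF5 at -0.052, CHRM3 at 0.18 and CHRM4 at -0.52. With pilocarpine library 1 also left out, HIST1H2BK was at -0.18, ATF5 at -0.074, IER3 at -0.061, CHRM3 at 0.17 and CHRM4 at -0.47. CHRM4 was also at -0.17 without pilocarpine libraries 3 and 4, and ran from -0.066 to 0.28 without single libraries. Of the called lists, cytosolic ribosomal proteins passed in 20 of 23 settings (median 0.19 to 0.80), glycolysis and hypoxia in 21 (0.14 to 0.35), oxidative phosphorylation in 18 (0.030 to 0.42) and histones in 17 (0.32 to 0.60). With an estimated correlation none passed: ribosomal (0.66), glycolysis (0.29) and histones (0.53) had an adjusted p of 0.652 and oxidative phosphorylation (0.30) one of 0.694. By fry's directional test, which compares no list with other genes, the same medians of 0.66, 0.29, 0.53 and 0.30 had adjusted p-values of 0.134, 0.0823, 0.0908 and 0.176. By fry's test of change in either direction, ribosomal (0.66) and oxidative phosphorylation (0.30) did not pass, at 0.0524 and 0.0907. Lists not called by camera that passed this test, at an adjusted p of 0.0441 to 0.0481, had these medians: EGF receptors and ligands -0.32, FOXO targets -0.063, G1/S and DNA replication -0.050, G2/M and mitosis -0.13, MAPK output -0.013, NF-kB 0.28, NRF2 targets 0.30, YAP-TEAD targets -0.21, calcium and G protein signalling -0.036, stem cell markers -0.16, cholesterol synthesis 0.18, epithelial markers 0.17, fatty acid synthesis -0.085, heat shock -0.022, immediate early genes -0.069, leukocyte markers 0.35, lysosome 0.27, mesenchymal markers 0.11, long noncoding RNAs -0.24, p53 targets 0.14, endocrine markers 0.25, type I interferon response 0.34 and xenobiotic metabolism -0.0064. Histones did not pass with a minimum of 50 counts (0.37, adjusted p = 0.118, fewer genes tested), with the trend removed (0.34, 0.231), or with pilocarpine library 1 also left out (0.32, 0.3999). Oxidative phosphorylation did not pass without pilocarpine libraries 3 and 4 (0.030, 0.504). The lysosome list passed by DESeq2 (0.26, 0.0365), without a filter (0.26, 0.0199), by library totals (0.18, 0.0494) and with the trend removed (0.087, 0.0418). Without a filter NF-kB (0.27, 0.0324), YAP-TEAD targets (-0.22, 0.0411) and type I interferon (0.26, 0.0280) passed. Removal of the trend also let G2/M (-0.11, 0.0418), NRF2 targets (0.12, 0.0499), YAP-TEAD targets (-0.16, 0.0026), immediate early genes (-0.27, 0.0025) and type I interferon (0.23, 0.0066) pass. With pilocarpine library 1 also left out, G2/M (-0.12, 0.0394), YAP-TEAD targets (-0.17, 0.0023) and immediate early genes (-0.30, 0.0296) passed. With an estimated correlation no list passed with the trend removed (lowest adjusted p 0.570, with 0.694 for NRF2 targets and 0.770 for G2/M) or with pilocarpine library 1 also left out (lowest 0.769). Without pilocarpine libraries 3 and 4, NF-kB (0.19, 0.0305) and type I interferon (0.23, 0.0257) passed. Over single libraries left out, medians ran from 0.42 to 0.60 for histones (adjusted p up to 0.0674), 0.11 to 0.25 for cholesterol synthesis (from 0.0473), 0.20 to 0.34 for lysosome (from 0.0218), 0.20 to 0.42 for oxidative phosphorylation (up to 0.0636), 0.20 to 0.39 for NF-kB (from 0.0220) and 0.15 to 0.37 for type I interferon (from 0.0220). At 18.7 to 27.8 M counts per library, depth limits the receptor genes, of which CHRM1, CHRM2 and CHRM5 had at most 3 counts in total.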

Other observations

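The fits in this part, with the GC and length trend removed, were chosen after the data were seen, as were the list members named here, EGFR and the neighbouring genes. The fit without pilocarpine library 1 leaves out the pilocarpine library nearest to the untreated ones, so its adjusted p-values can be too small. With pilocarpine library 1 also left out, targets of the YAP and TEAD growth regulators fell as a group: 10 of 23 tested genes fell, with a list median of -0.17 (camera adjusted p = 0.0023, and adjusted p = 0.769 with an estimated correlation). Among them were CTGF, a matricellular protein (log2 fold change -0.55, SE 0.16, adjusted p = 0.0243), and the kinase gene LATS2 (-0.55, SE 0.12, adjusted p = 0.0062). Immediate early genes had a list median of -0.30 (adjusted p = 0.0296, and adjusted p = 0.769 with an estimated correlation), and 4 of 17 fell: the transcription factor genes EGR1 (-0.94, SE 0.26), EGR3 (-1.90, SE 0.52) and ATF3 (-0.40, SE 0.10) and the mRNA decay factor ZFP36 (-0.57, SE 0.16). In the G2/M and mitosis list 13 of 40 genes fell and 5 rose, with a median of -0.12 (adjusted p = 0.0394, and adjusted p = 0.769 with an estimated correlation). The falls included TOP2A (-0.42, SE 0.09), CENPF (-0.39, SE 0.10) and MKI67 (-0.36, SE 0.10), and the rises BUB3 (0.61, SE 0.10) and BIRC5 (0.32, SE 0.08). As scaled, the fold changes within this list followed the trend fitted on all other genes, with a Spearman correlation of 0.920. Whether a remainder of that trend separates these falls and rises in the fit without pilocarpine library 1 was not tested. EGFR, the receptor of epidermal growth factor, had 250 CPM without and 120 CPM with pilocarpine, a log2 fold change of -1.06 (SE 0.34, adjusted p = 0.0622) over all 8 libraries as scaled and -1.0 (SE 0.15, adjusted p = 0.0021) in this fit. Over all 8 libraries with the trend removed, the list medians were -0.16 for YAP-TEAD targets (adjusted p = 0.0026), -0.27 for immediate early genes (adjusted p = 0.0025) and -0.11 for G2/M (adjusted p = 0.0418). With an estimated correlation the adjusted p was 0.570, 0.570 and 0.770. EGFR was at -0.74 (adjusted p = 0.0964) in that fit. The groups overlapped in the mean of each of these 3 lists per library, with an exact permutation p of 0.0571 for YAP-TEAD targets, 0.114 for immediate early genes and 0.114 for G2/M (Benjamini-Hochberg 0.229, 0.244 and 0.244). For immediate early genes, untreated library 4 had a mean of -0.414 relative to the untreated mean (log2), below the -0.246, -0.353 and -0.213 of pilocarpine libraries 1, 2 and 4.

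In the fit of all 8 libraries without the trend, 5 of 32 lists had a mean in all 4 pilocarpine libraries above all 4 untreated libraries, library 1 included, and 0 had it below. Chance gives 0.914 lists apart in either direction on average. All lists were scored in the same 8 libraries and can move together, so setting 5 beside 0.914 does not measure an excess. The type I interferon response had a mean of 0.21 ± 0.11 (log2, SD, n = 4, relative to the untreated mean), with pilocarpine library 1 at 0.20 and the highest untreated library at 0.074. The other 4 were replication-dependent histones (0.19 ± 0.11), glycolysis and hypoxia (0.14 ± 0.07), lysosome and autophagy (0.11 ± 0.06) and NRF2 targets (0.10 ± 0.08). For each, the two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 can give, and a Benjamini-Hochberg value of 0.183 over the 32 lists, so none passed after correction.

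In untreated PANC1 cells, which are known to carry extra copies of the AKT2 segment of chromosome 19, the 25 neighbouring expressed genes from NFKBIB to PSMC4 on that chromosome had a median log2 CPM of 8.00. This was the highest of 11812 windows of 25 genes, whose median was 5.09, and the next separate window, from FAM89B to RAB1B on chromosome 11, was at 7.18. Its most abundant genes were RPS16 (5172 ± 426 CPM), the proteasome gene PSMC4 (2373 ± 156 CPM) and the nucleolar methyltransferase gene FBL (2242 ± 155 CPM). The elongation factor gene SUPT5H (2102 ± 59.6 CPM) and PLEKHG2 (1712 ± 234 CPM) came next. The lowest in the window were GMFG (0.924 ± 0.206 CPM), FCGBP (2.18 ± 0.352 CPM) and NCCRP1 (2.65 ± 0.582 CPM). AKT2 itself, which is not among the genes of this window, had 2323 CPM. No copy numbers were measured here.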
